A study of Arabidopsis thaliana with 24 samples.

How the data were processed

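Transcript levels were measured in germinating Arabidopsis thaliana seeds on Affymetrix ATH1 arrays, in which each probe set, a group of short oligonucleotides, reports 1 transcript or a few related ones. The 24 arrays formed 4 groups of 6, and every array was assigned to its group from its label. The groups were Columbia wild type and the pkl mutant, each with solvent only or with uniconazole. Per the labels' protocols the medium held 0.01% methanol as solvent or 10 nM uniconazole in it, seeds germinated under continuous light, and RNA came from a hot phenol extraction followed by lithium chloride precipitation and a column clean-up. The labels give neither the age of the seeds at harvest nor the pkl allele.

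The deposited values are linear probe set intensities. Per the submitters' processing notes they were made with MAS5, whose version and settings are not given in the sources used here. In the deposited intensity table the mean after trimming 2% of the values at each end was 1000.1 on every array, so the arrays had been scaled to a common trimmed mean. No detection calls, scanner images or scan dates were used here. All value columns belonged to the 24 arrays.

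Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested. GEO's platform annotation paired 13513 of these with 1 gene and 503 with several, and it did not list 8730, which are unnamed here. Symbols were updated through a RefSeq gene table of assembly TAIR10.1, in which 13436 of the 13513 were found, and 1580 had a symbol as well as a locus code. Because the deposited table names no genome build, no coordinates are given and genes are identified by locus code. Among 147 genes with more than 1 probe set, 0 had probe sets past the threshold in opposite directions in a contrast between 2 groups. PKL, the gene affected in the mutant, was not analysed here, so its own transcript gives no check of the genotype labels.

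Tests ran on log2(signal + 16). The offset of 16 damps noise in low signals and understates fold changes of dim probe sets, so log2 changes are on this scale, while signals are given on the deposited linear scale as mean and SD. All 4 groups entered 1 limma fit (lmFit, then eBayes with a variance trend, 20 residual degrees of freedom). The contrasts were the pkl effect in solvent, the pkl effect in uniconazole, the uniconazole effect in wild type, the uniconazole effect in pkl, and their interaction, the pkl effect in uniconazole minus that in solvent. P-values are two-sided and Benjamini-Hochberg adjusted within each contrast, with a threshold of 0.05. Every adjusted p given for a gene is from this fit. The number of arrays limits the precision.

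Background was taken from 27 probe sets for bacterial control transcripts. The 95th percentile of their 648 values was 54.9, and this is called the bacterial control level. Where 1 of the 2 groups compared had a mean at or under it, a fold is given as a lower bound, the brighter mean over 54.9, and where both did, no fold is given. RNA integrity was followed with the log2 ratio of 3′ to 5′ control probe sets for GAPDH, actin and ubiquitin.

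Gene lists were tested with camera, which asks whether members shift relative to other probe sets, at a preset correlation of 0.01 and again with an estimated correlation, with 1 probe set per gene and adjustment over the 56 lists tested within a contrast. Lists with at least 3 named members were tested. Of 18 lists (256 genes) fixed before the data were examined, 29 genes were named on the array and 5 lists could be tested. They were embryo regulators, late embryogenesis abundant genes, gibberellin signalling, cell wall expansion and photosynthesis. The lists of storage and oil-body proteins, reserve mobilisation, root hair, testa and flavonoid, endosperm, cell division, and stress and pathogen response had 1 or 2 named members, and their members are reported singly. The lists of seed lipid synthesis, gibberellin metabolism, abscisic acid, brassinosteroid, Polycomb-silenced regulators and chromatin factors had 0 named members and were not analysed here. A further 51 lists were drawn from the annotation after it was seen and before any group difference was computed. Of these, 44 were families of genes sharing a symbol stem, and 7 were groups such as seed maturation genes, gibberellin receptors and regulators, nuclear photosynthesis genes, flavonoid genes, chloroplast-encoded genes, mitochondrion-encoded genes and annotated pseudogenes. Some genes belong to more than 1 list, so the calls of overlapping lists are not independent. GID1A, GID1B and SLY1, for example, are in both gibberellin lists, and XTH18 and XTH33 are in the cell wall list and the XTH family. A list score is the mean log2(signal + 16) of its members on an array, and its standard error pools the spread within the 4 groups.

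Named genes followed a rule set before the data were examined. In each contrast between 2 groups they were the 8 higher and 8 lower probe sets with the largest log2 change past the threshold that had 1 gene and a symbol, and for the interaction up to 5 in each direction. From each list described, up to 4 members past the threshold with the smallest adjusted p were added, or the 2 with the smallest p where none passed. Probe sets with no symbol were passed over, in the pkl comparison in solvent 71 among the higher and 78 among the lower ones.

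Alternatives planned beforehand were quantile normalization, scaling to one median, offsets of 1 and 64, a filter keeping probe sets above the 40th percentile of mean signal, no variance trend, only the groups compared, the replicate number as a block, array weights, a threshold of 0.01 and, for lists, an estimated correlation and the mean of all probe sets of a gene. Added after seeing the data were fits without single arrays, with the share of probe sets under a signal of 16 as a covariate, and with the 3′/5′ ratios of GAPDH and actin as covariates. For the score of the chloroplast-encoded genes the ratio of ubiquitin was also added. Whether probe sets followed a covariate within groups was tested in limma, and again for 99 exchanges of its values between arrays of a group. For each contrast, 100 splits of the arrays were drawn, the real one included. For the interaction these redrew treatments within genotypes, and a further 100 arrangements, added after seeing the data, exchanged arrays after removing the genotype and treatment effects. The fit was tested on simulated data with the layout of the pkl comparison in solvent over 22746 probe sets. It recovered 74% of 50 changes of 0.5, 96% of 50 changes of 1, and 100% of 50 changes each of 2 and -1 (log2). Of 196 calls 11 were false. The changes were placed only in probe sets with a mean above the median, so recovery among dimmer ones was not tested. The simulated noise was independent between probe sets and had the same spread in every group. In the real data 566 probe sets followed the share under 16 within groups, so the simulated share of false calls need not hold there. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.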

Results

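Transcript levels were compared in germinating Arabidopsis seeds of the wild type (Columbia) and of the pickle mutant (pkl), germinated with solvent or with 10 nM uniconazole. PICKLE is a CHD3-type chromatin remodelling factor, and uniconazole is a triazole growth retardant that inhibits gibberellin synthesis. Each of the 4 groups held 6 arrays, described by the submitters as biological replicates. Median signals of the arrays ranged from 310.2 to 371.4, and between 9.1% and 13% of the probe sets of an array lay under a signal of 16. The log2 3′/5′ ratio of GAPDH, a measure of RNA integrity, was 0.36 ± 0.06 in wild type with uniconazole and 0.26 ± 0.08 in wild type with solvent (SD, n = 6; exact permutation test, two-sided p = 0.026, adjusted p = 0.152 over 20 such comparisons). The ratio of ubiquitin was 0.77 ± 0.11 in pkl with uniconazole and 0.63 ± 0.07 in pkl with solvent (exact permutation p = 0.0303, adjusted p = 0.152). The median signal was 364.57 ± 5.42 in pkl with uniconazole and 345.08 ± 8.46 in pkl with solvent (SD, n = 6; exact permutation p = 0.00216, adjusted p = 0.0433), and 344.48 ± 18.49 in wild type with uniconazole (exact permutation p = 0.00649 against pkl with uniconazole, adjusted p = 0.0649).

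The comparison of pkl with wild type in solvent asked which transcripts differ between the genotypes in germinating seeds. A difference in stage of germination was not separated from an effect of the mutation, since the age at harvest is not given. PDF2.1 (AT2G02120), a plant defensin, had a signal of 1765 ± 261 in pkl and 266 ± 48.7 in wild type (SD, n = 6), a log2 change of 2.67 ± 0.11 (SE, adjusted p = 2.48e-15). PAP85 (AT3G22640), a vicilin-like seed storage protein, had 1000 ± 168 in pkl and 167 ± 30.2 in wild type (log2 change 2.47 ± 0.14, adjusted p = 1.00e-12). M10 (AT2G41280), a late embryogenesis abundant protein of maturing seeds, had a signal of 269 ± 79.1 in pkl. Its wild-type mean of 45.8 ± 26.7 was under the bacterial control level, which makes the difference at least 4.90-fold (log2 change 2.26 ± 0.30, adjusted p = 5.42e-06). Every pkl array exceeded every wild-type array for these 3 genes.

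The other genes named as higher in pkl were the peroxidase gene PRX52 (log2 change 2.00), the chloroplast-encoded ndhG (1.79), QQS (1.77), ALPHA-VPE (1.66), which encodes a vacuolar processing protease, and the dehydrin gene LTI30 (1.45). For ALPHA-VPE, 4 of 6 pkl arrays lay above all wild-type arrays, and the wild-type mean of 37.6 was under the bacterial control level, which makes the difference at least 2.47-fold. Genes lower in pkl were led by CHL (AT3G47860), which encodes a chloroplast lipocalin, with 165 ± 42.1 in pkl against 942 ± 132 in wild type (SD, n = 6; log2 change -2.44 ± 0.17, adjusted p = 2.87e-11). RSU1 (log2 change -1.69), the auxin-conjugating enzyme genes GH3.3 (-1.61) and GH3.1 (-1.2), the xyloglucan-modifying enzyme gene XTH32 (-1.39) and PORB (-1.24), a light-dependent enzyme of chlorophyll synthesis, also fell. The pkl mean of GH3.3, 44.6, was under the bacterial control level, so it was at least 3.04-fold lower. CLE26 and BLT passed the test at low signals. BLT had 10.6 ± 7.5 in pkl and 45.9 ± 17.7 in wild type, both under the bacterial control level, and CLE26 was at least 1.06-fold lower in pkl.

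Both named members of the fixed list of storage and oil-body proteins passed in solvent, in opposite directions. PAP85 rose, while OLEO3, an oleosin of seed oil bodies, fell from 2068 ± 327 to 1384 ± 208 (SD, n = 6; log2 change -0.57 ± 0.10, adjusted p = 1.52e-04). Among the 15 seed maturation genes drawn from the annotation, 3 rose, 1 fell and 11 did not pass, with a mean log2 change of 0.38 and a median of 0.07 (camera adjusted p = 0.222). The fixed list of late embryogenesis abundant genes had 1 of 4 members higher, M10, and the same number adjusted over the list alone (camera adjusted p = 0.714, mean 0.46, median -0.05). Of the 17 nuclear photosynthesis genes, 5 fell, 1 rose and 11 did not pass. Their mean log2 change was -0.26 (camera adjusted p = 0.00936; adjusted p = 0.771 with an estimated correlation). LHCB4.2, a light-harvesting antenna gene, fell by 1.17 on the log2 scale, and CHLI2, a subunit gene of magnesium chelatase, fell by 0.34, whereas SBPASE, of the Calvin cycle, rose by 0.52. In the fixed photosynthesis list 1 of 3 members was lower, PORB, and 3 adjusted over the list alone (camera adjusted p = 0.00936; adjusted p = 0.771 with an estimated correlation).

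Chloroplast-encoded genes moved the other way. Of 69 measured, 15 rose, 0 fell and 54 did not pass, with a median log2 change of 0.17 (camera adjusted p = 3.63e-04; adjusted p = 0.812 with an estimated correlation). ndhG had a signal of 2338 ± 605 in pkl and 683 ± 255 in wild type, petD 1059 ± 283 and 392 ± 143, and rps14 770 ± 202 and 311 ± 86.0 (SD, n = 6). In the fixed lists, the expansin gene EXPA4 (log2 change 0.39) and XTH33 (0.79) were higher among 4 cell wall expansion genes, 2 adjusted over the list alone (camera adjusted p = 0.0867). Among 4 gibberellin signalling genes, GID1A (0.42), a gibberellin receptor gene, and SLY1 (0.43), an F-box gene of the pathway, rose and the receptor gene GID1B (-0.52) fell, the same 3 adjusted over the list alone (camera adjusted p = 0.411). Of the 14 embryo regulators only 3 were named on the array, BBM, AGL18 and EEL. LEC1, LEC2, FUS3 and ABI3 were not among them, so nothing is said of these. None of the 3 passed, 0 adjusted over the list alone (camera adjusted p = 0.983).

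In total 1542 probe sets were higher and 1130 lower in pkl than in wild type in solvent, and 365 of them had a log2 change of at least 1 in size, against 182 with an offset of 64 and 192 with the filter on low signal. With arrays scaled to one median the split was 1131 higher and 1437 lower. Of the 2672 called, 1419 had 1 gene and 249 a symbol.

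**Figure D1:**
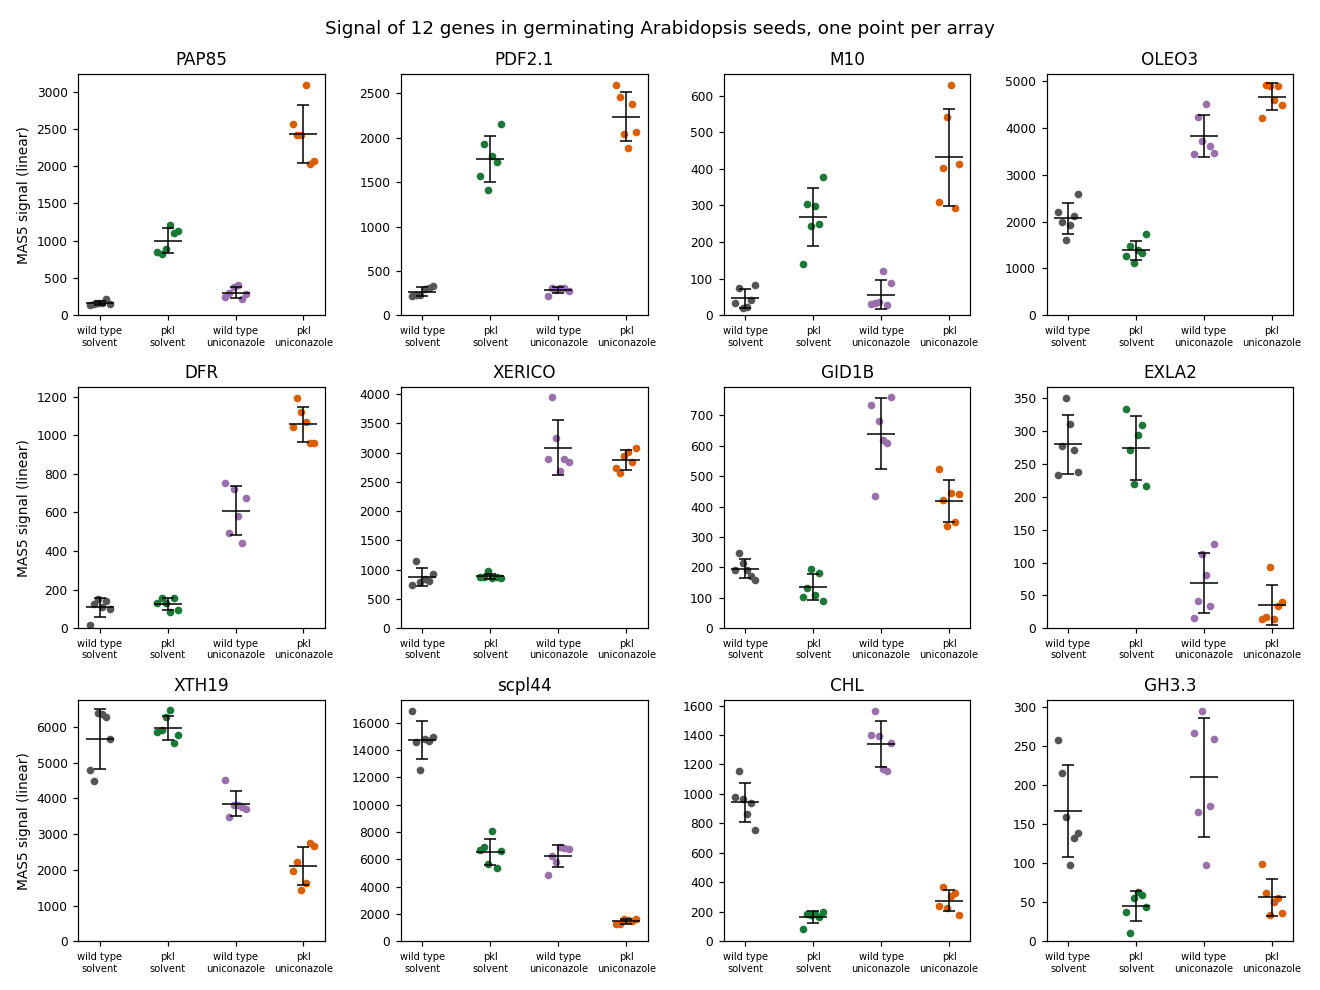
Linear MAS5 signal (y axis, starting at 0) of 12 genes in the 4 groups (x axis), with 1 point per array, the mean as a horizontal line and the SD as bars (n = 6). PAP85 rose from a mean of 167 in wild type with solvent to 2428 in pkl with uniconazole, and scpl44 fell from 14723 to 1452.

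The same genotypes were compared in uniconazole, which asked how the mutant differs when gibberellin synthesis is inhibited. PAP85 had 2428 ± 387 in pkl and 304 ± 75.8 in wild type (SD, n = 6; log2 change 2.95 ± 0.14, adjusted p = 2.25e-14), PDF2.1 rose by 2.91 and M10 by 2.74 on the log2 scale. BGLU19, a beta-glucosidase gene, had 1476 ± 544 in pkl and 292 ± 85.2 in wild type (log2 change 2.24 ± 0.22, adjusted p = 3.78e-08). HIS1-3, a linker histone gene, rose by 1.86 and the defensin gene PDF1.4 by 1.83. With wild-type means under the bacterial control level, ALPHA-VPE was at least 3.59-fold and the RING-type gene ATL5 at least 3.09-fold higher in pkl (adjusted p = 2.12e-04 and 5.30e-05). Of the genes that fell, RSU1 changed by -2.36, CHL by -2.25, the serine carboxypeptidase-like gene scpl44 by -2.08, GH3.3 by -1.63 and the transcription factor gene BZIP61 by -1.51. With pkl means under the bacterial control level, ECS1 was at least 2.03-fold and GH3.1 at least 1.56-fold lower in pkl (adjusted p = 8.56e-05 and 0.00211). scpl44 (AT1G43780) had 1452 ± 169 in pkl and 6222 ± 809 in wild type (SD, n = 6; adjusted p = 1.46e-14). BGLU46 also passed, with both means under the bacterial control level.

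Seed maturation genes were shifted upwards in pkl with uniconazole. Of 15, 8 rose, 0 fell and 7 did not pass, with a mean log2 change of 0.70 and a median of 0.30 (camera adjusted p = 1.19e-04; adjusted p = 0.351 with an estimated correlation). They included PAP85, M10, LTI30 (1.71) and BETA-VPE (0.39), a vacuolar processing protease gene of seeds. OLEO3 rose by 0.29 (adjusted p = 0.0357), so that both named storage and oil-body genes were higher. In the fixed list of late embryogenesis abundant genes 2 of 4 rose, M10 and COR15A, 2 adjusted over the list alone (camera adjusted p = 0.115). COR15A had a mean of 43.4 in pkl and 13.1 in wild type, both under the bacterial control level. EEL, a bZIP factor gene of maturing seeds, was the 1 of 3 embryo regulators that rose (0.44), also 1 adjusted over the list alone (camera adjusted p = 0.869).

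Chloroplast-encoded genes were higher in pkl with uniconazole as well: 32 of 69 rose, 0 fell and 37 did not pass. Their mean log2 change was 0.51 ± 0.14 (SE; camera adjusted p = 2.21e-11; adjusted p = 0.644 with an estimated correlation). With the share of probe sets under a signal of 16 as a covariate, chosen after seeing the data, it was 0.39 ± 0.12. psbB had 3343 ± 752 in pkl against 1222 ± 930 in wild type, and psbD 2973 ± 420 against 1687 ± 587 (SD, n = 6). Of 17 nuclear photosynthesis genes 7 fell, 1 rose and 9 did not pass (camera adjusted p = 0.0412; adjusted p = 0.674 with an estimated correlation), with CHLI2 at -0.54, CHLM at -0.50 and PSBY at -0.49. The fixed photosynthesis list had 2 of 3 members lower, PORB (-0.65) and RCA (-0.34), and 2 adjusted over the list alone (camera adjusted p = 0.104). In the XTH family of xyloglucan-modifying enzymes, 4 of 9 fell and 1 rose (camera adjusted p = 0.0383; adjusted p = 0.442 with an estimated correlation). XTH32 fell by 1.37 and XTH19 by 0.90 on the log2 scale, and XTH33 rose by 0.56. Among the 4 cell wall expansion genes 1 was higher, 1 adjusted over the list alone (camera adjusted p = 0.91). The 4 gibberellin signalling genes had 2 higher and 1 lower, as adjusted over the list alone (camera adjusted p = 0.267). EXPA7 and EXPA18, the root hair expansin genes measured, rose by 0.90 and 0.89.

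With uniconazole 2246 probe sets were higher and 1976 lower in pkl than in wild type, 481 of them with a log2 change of at least 1 in size, against 241 with an offset of 64 and 224 with the filter on low signal. Scaling to one median gave 1570 higher and 2830 lower. Across probe sets the pkl effects with and without uniconazole, which share no arrays, correlated with Pearson's r = 0.59 and Spearman's rho = 0.50. Genes are not independent replicates, and no p is given. Both contrasts called 1022 probe sets higher, against 152.3 for independent lists, and 793 lower, against 98.2, with 5 called in opposite directions.

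**Figure D2:**
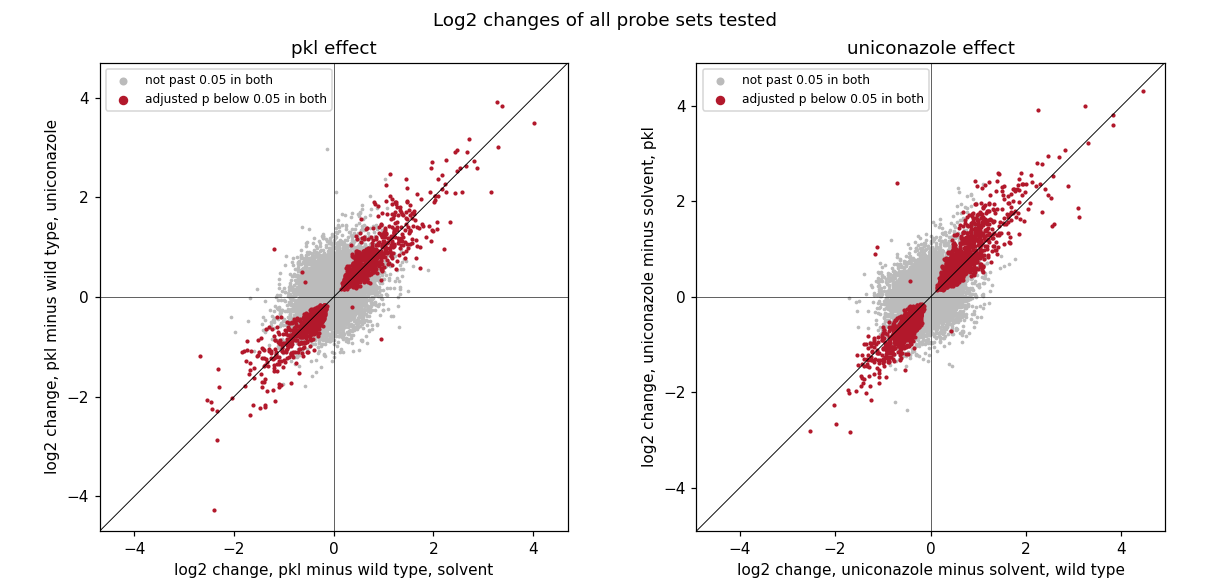
Log2 changes of all probe sets tested, in solvent (x axis) and uniconazole (y axis) for the pkl effect on the left, and in wild type (x axis) and pkl (y axis) for the uniconazole effect on the right; red points had an adjusted p below 0.05 in both contrasts of a panel, and the diagonal marks equal change. Pearson's r was 0.59 on the left and 0.63 on the right.

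Uniconazole was compared with solvent in wild type to find the transcripts that respond to the inhibitor. The largest rise among genes with a symbol was that of DFR (AT5G42800), dihydroflavonol reductase of anthocyanin synthesis. It had 610 ± 126 with uniconazole and 108 ± 48.0 with solvent (SD, n = 6; log2 change 2.47 ± 0.26, adjusted p = 7.63e-08). UF3GT (AT5G54060), an anthocyanin glycosyltransferase gene, had 694 ± 161 and 171 ± 36.7 (log2 change 1.92 ± 0.17, adjusted p = 5.86e-09). XERICO (AT2G04240), a RING-type gene linked to gibberellin and abscisic acid, rose from 877 ± 148 to 3084 ± 466 (log2 change 1.80 ± 0.09, adjusted p = 2.44e-14). GID1B (AT3G63010) rose from 196 ± 32.0 to 640 ± 117 (log2 change 1.62 ± 0.17, adjusted p = 6.18e-08). The cytochrome P450 gene CYP71B26 (2.00), IQD24 (1.55) and the seed gene M17 (1.31) were also higher. NET3C, under the bacterial control level in solvent, was at least 1.79-fold higher.

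Of the genes that fell, the expansin-like gene EXLA2 had 68.9 ± 45.6 with uniconazole and 280 ± 44.6 with solvent (SD, n = 6; log2 change -1.99 ± 0.32, adjusted p = 4.34e-05), EXO had 827 ± 116 and 2244 ± 102 (-1.43 ± 0.08, adjusted p = 1.17e-12), and XTH18 had 372 ± 102 and 990 ± 177 (-1.40 ± 0.17, adjusted p = 6.59e-07). BZIP61 (-1.69), P1R3 (-1.39), scpl44 (-1.25) and WAG2 (-1.18), a protein kinase gene, fell too. YUC6, an auxin synthesis gene, was at least 2.43-fold lower, with a treated mean under the bacterial control level (adjusted p = 0.0155).

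All 6 treated wild-type arrays lay above the untreated ones in the score of the gibberellin receptors and regulators. Of the 7 genes 5 rose and 2 did not pass, with a mean log2 change of 0.74 ± 0.04 (SE; camera adjusted p = 3.17e-06; adjusted p = 0.00134 with an estimated correlation). GID1A rose from 753 ± 95.8 to 1582 ± 67.3 and SLY1 from 859 ± 70.5 to 1331 ± 65.6 (SD, n = 6). In the fixed gibberellin signalling list 3 of 4 rose, and 3 adjusted over the list alone (camera adjusted p = 2.34e-05; adjusted p = 0.00689 with an estimated correlation). Cell wall expansion genes fell in 3 of 4 cases, and in 4 adjusted over the list alone (camera adjusted p = 1.77e-04; adjusted p = 0.0416 with an estimated correlation). Besides XTH18 they were EXPA8 (-0.82) and XTH33 (-0.91). The XTH family had 4 of 9 lower and 1 higher (camera adjusted p = 0.0432; adjusted p = 0.275 with an estimated correlation), with XTH16 at -0.84 and XTH32 at 0.96. Of 5 beta-tubulin genes 3 fell, TUB1 (-0.35), TUB5 (-0.26) and TUB7 (-0.46) (camera adjusted p = 0.0114; adjusted p = 0.0558 with an estimated correlation).

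Seed maturation genes rose in 7 of 15 cases and fell in 0 (mean log2 change 0.40 ± 0.08, SE; camera adjusted p = 1.69e-05; adjusted p = 0.0547 with an estimated correlation). LEA4-5 rose from 5944 ± 1020 to 10941 ± 1626, LEA18 from 8633 ± 1202 to 14800 ± 1873 and OLEO3 from 2068 ± 327 to 3827 ± 440 (SD, n = 6), and PAP85 rose by 0.79 on the log2 scale. In the fixed list of late embryogenesis abundant genes, 2 of 4 rose, M17 and LEA4-5, 2 adjusted over the list alone (camera adjusted p = 0.0432; adjusted p = 0.275 with an estimated correlation). EEL rose by 0.83, the 1 embryo regulator of 3 that passed over all probe sets, against 2 adjusted over the list alone (camera adjusted p = 0.167). Nuclear photosynthesis genes rose in 12 of 17 cases and fell in 0 (mean log2 change 0.40 ± 0.08, SE; camera adjusted p = 1.90e-08; adjusted p = 0.171 with an estimated correlation). LHCB4.1 had 4235 ± 699 with uniconazole and 2689 ± 320 with solvent, and PRK 2261 ± 320 and 1484 ± 162 (SD, n = 6). The fixed photosynthesis list had 2 of 3 higher, 2 adjusted over the list alone (camera adjusted p = 0.0618). Flavonoid genes rose in 4 of 7 cases, DFR, UF3GT, UGT78D2 (0.37) and CHIL (0.29) (camera adjusted p = 0.0114; adjusted p = 0.271 with an estimated correlation). Chloroplast-encoded genes had 4 of 69 higher, among them rbcL at 0.55 (camera adjusted p = 0.00591; adjusted p = 0.82 with an estimated correlation). In the NET family of actin-binding proteins 2 of 10 rose, NET3C and NET1B (0.81) (camera adjusted p = 0.0464; adjusted p = 0.275 with an estimated correlation).

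In wild type 2064 probe sets were higher and 1691 lower with uniconazole, and 358 had a log2 change of at least 1 in size, against 171 with an offset of 64 and 196 with the filter on low signal. With arrays scaled to one median there were 1411 higher and 2187 lower. With the GAPDH and actin 3′/5′ ratios as covariates, an alternative chosen after seeing the data, 2422 probe sets passed in place of 3755, and 359 in place of 358 had a log2 change of at least 1 in size.

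**Figure D3:**
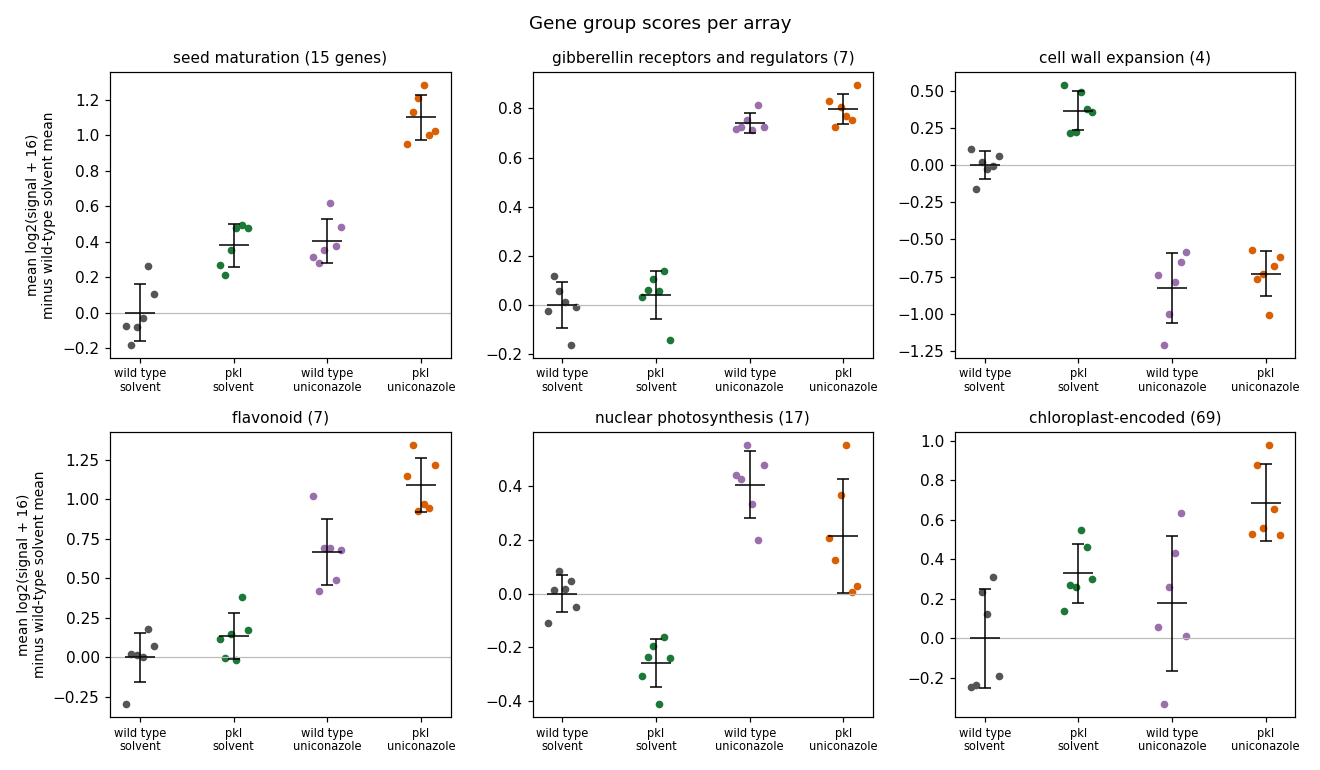
Score of 6 gene groups per array, the mean log2(signal + 16) of the members minus the mean of the wild-type solvent arrays (y axis, log2 units), in the 4 groups (x axis), with the mean as a line and the SD as bars (n = 6). The gibberellin receptors and regulators were higher with uniconazole by 0.74 in wild type and 0.75 in pkl, and chloroplast-encoded genes spread widely within groups.

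In pkl, uniconazole was compared with solvent in the same way. DFR had 1057 ± 90.5 with uniconazole and 125 ± 30.9 with solvent (SD, n = 6; log2 change 2.96 ± 0.26, adjusted p = 1.64e-09), and UF3GT and CYP71B26 each rose by 2.36 on the log2 scale. OLEO3 rose from 1384 ± 208 to 4667 ± 286 (log2 change 1.75 ± 0.10, adjusted p = 2.42e-13), and XERICO from 889 ± 40.7 to 2874 ± 166 (1.67 ± 0.09, adjusted p = 8.77e-14). AOP3, a glucosinolate gene, rose by 2.06. The pectin methylesterase gene PMEPCRF was at least 3.80-fold and CHR42 at least 3.18-fold higher, with solvent means under the bacterial control level. BZIP61 had 90.9 ± 62.6 with uniconazole against 608 ± 81.2 with solvent (-2.84 ± 0.32, adjusted p = 1.31e-07), and EXLA2, 35.0 ± 30.2 against 275 ± 48.2, was at least 5.01-fold lower. scpl44 fell by 2.15, WAG2 by 1.61, XTH19 by 1.54, XTH18 by 1.44, EXO by 1.40 and the asparaginase gene ASPGB1 by 1.39 on the log2 scale.

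Of the 7 gibberellin receptors and regulators, 4 rose in pkl and 0 fell (mean log2 change 0.75 ± 0.04, SE; camera adjusted p = 2.69e-05; adjusted p = 0.00535 with an estimated correlation). GID1A rose by 1.2, GID1B by 1.56 and SLY1 by 0.63. The fixed gibberellin signalling list had 3 of 4 higher, 3 adjusted over the list alone (camera adjusted p = 6.85e-05; adjusted p = 0.00957 with an estimated correlation). All 4 cell wall expansion genes fell, 4 adjusted over the list alone (camera adjusted p = 4.91e-06; adjusted p = 0.00957 with an estimated correlation). EXPA8 fell by 1.26, XTH33 by 1.14 and EXPA4 by 0.55. Of 5 beta-tubulin genes 4 fell, with TUB7 at -0.68 (camera adjusted p = 0.00234; adjusted p = 0.0208 with an estimated correlation). The XTH family had 5 of 9 lower and 2 higher (camera adjusted p = 0.0205; adjusted p = 0.221 with an estimated correlation). In the PRA family, of prenylated Rab acceptor proteins, 5 of 11 fell and 0 rose, with PRA1.B4 at -0.66 (camera adjusted p = 0.0232; adjusted p = 0.454 with an estimated correlation).

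Seed maturation genes rose in 9 of 15 cases and fell in 0 (mean log2 change 0.72 ± 0.08, SE; camera adjusted p = 1.31e-07; adjusted p = 0.0127 with an estimated correlation), with LEA4-5 at 1.14, LEA18 at 1.02, PAP85 at 1.27 and M17 at 1.57. The fixed list of late embryogenesis abundant genes had 2 of 4 higher, and 4 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.1 with an estimated correlation). EEL rose by 1.36, 1 of 3 embryo regulators and also 1 adjusted over the list alone (camera adjusted p = 0.249). Nuclear photosynthesis genes rose in 12 of 17 cases (camera adjusted p = 1.10e-06; adjusted p = 0.214 with an estimated correlation), led by LHCB4.2 at 1.22 and PSAE-1 at 1.05. All 3 genes of the fixed photosynthesis list rose, 3 adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.335 with an estimated correlation). Flavonoid genes rose in 3 of 7 cases (camera adjusted p = 0.00321; adjusted p = 0.168 with an estimated correlation) and chloroplast-encoded genes in 22 of 69 (camera adjusted p = 1.31e-07; adjusted p = 0.695 with an estimated correlation), with rps4 at 0.66. Of the genes of reserve mobilisation, SDP1, a triacylglycerol lipase gene, fell by 0.33, and ICL, isocitrate lyase, had a log2 change of -0.00 ± 0.08 (SE, adjusted p = 0.984).

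In pkl 2594 probe sets were higher and 2405 lower with uniconazole, 628 of them with a log2 change of at least 1 in size, against 406 with an offset of 64 and 390 with the filter on low signal. Scaling to one median gave 1747 higher and 3169 lower. The uniconazole effects in wild type and in pkl share no arrays, and across probe sets they correlated with Pearson's r = 0.63 and Spearman's rho = 0.53. Both contrasts called 1503 probe sets higher, against 235.4 for independent lists, and 1307 lower, against 178.8, with 5 in opposite directions.

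The interaction tested whether the pkl effect differed between uniconazole and solvent. OLEO3 was lower in pkl in solvent and higher in pkl with uniconazole, a difference of 0.86 ± 0.14 on the log2 scale (SE, adjusted p = 0.00371). LEA (AT2G21490), a dehydrin gene, had a signal of 1338 ± 213 in wild type and 1614 ± 256 in pkl with solvent, and 2073 ± 322 and 4568 ± 644 with uniconazole (SD, n = 6; interaction 0.87 ± 0.17, adjusted p = 0.0223). The mutant had less scpl44 under both conditions, with an interaction of -0.91 ± 0.14 (adjusted p = 0.00211). XTH19, the 1 gene of the endosperm list named on the array, had 5665 ± 837 in wild type and 5980 ± 341 in pkl with solvent (SD, n = 6). With uniconazole it had 3858 ± 351 and 2106 ± 538 (SD, n = 6), and its interaction was -0.99 ± 0.17 (SE, adjusted p = 0.00902). These 4 were the called genes with a symbol.

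The interaction of the 15 seed maturation genes had a mean of 0.32 ± 0.11 (SE), with 1 member past the threshold, OLEO3 (camera adjusted p = 6.67e-04; adjusted p = 0.305 with an estimated correlation). That of the 69 chloroplast-encoded genes had a mean of 0.18 ± 0.20, smaller than its standard error, with 0 members past the threshold (camera adjusted p = 6.06e-04, and adjusted p = 0.834 with an estimated correlation). In the limma interaction 16 probe sets had a positive and 16 a negative difference. The total of 32 was 20 without wild-type solvent replicate 5 and 21 without wild-type uniconazole replicate 2, both chosen after seeing the data.

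The pkl effect in solvent was also set against the uniconazole effect in wild type, which use the same wild-type solvent arrays. In the calls, 447 probe sets were higher in both, against 139.9 for independent lists, and 279 were lower in both, against 84.0. Another 285 went in opposite directions, against 217.2. Shared controls raise the overlap in the same direction, so independent lists are too low a baseline for it. PAP85, GID1A and SLY1 were higher in both, and XTH16 was lower in both. XTH33 was higher in pkl and lower with uniconazole, while GID1B, XTH32 and OLEO3 were lower in pkl and higher with uniconazole. Pearson's r across probe sets was 0.29, against 0.50 for 100 simulations of unchanged groups sharing controls. With the controls split into 3 and 3, r was 0.07 on average over 20 splits, from -0.03 to 0.13. The covariance was 0.0350, against 0.0214 in the simulations, a difference of 0.0136, and 0.0100 with split controls. The simulations gave every group the pooled spread of a probe set, so 0.0136 is inexact if the wild-type solvent arrays spread differently. A shared group that enters with opposite signs lowers r. In that case r was 0.00 for the pkl effect in uniconazole and the uniconazole effect in wild type. For the pkl effect in solvent and the uniconazole effect in pkl it was -0.04.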

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

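The tests of the organelle explanation and of RNA integrity and array quality as the whole cause for the chloroplast-encoded genes, of an earlier stage of germination, and of other splits of the arrays were written down only after the results they bear on had been seen. The remaining tests in this part were written down before.

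Several values stood apart from the other arrays of their group of 6, by a gap larger than Dixon's 95% limit. Of 256 groups examined, 18 (7.0%) had such a value, and chance gives about 1 in 20. Wild-type solvent replicate 1 had a low DFR signal of 18 (the others 102 to 153), HIS1-3 of 16.3 (82.3 to 101), QQS of 16.7 (65.7 to 124) and BZIP61 of 653 (790 to 847), and a flavonoid score of 7.80 (8.10 to 8.27). In the same group ATL5 was 84.5 in replicate 2 and BGLU19 was 220 in replicate 3. In pkl with solvent, CHL was 82.0 in replicate 1, EXO 1278, GH3.3 10.8 and UF3GT 116 in replicate 2, CLE26 57.6 and XERICO 970 in replicate 3. The score of the gibberellin receptors and regulators was 9.35 in replicate 6, where the others had 9.53 to 9.63. In wild type with uniconazole, XTH19 was 4528 in replicate 1 and its score as the endosperm list 12.15, YUC6 was 130 in replicate 2, against 16.6 to 30.4, and P1R3 was 10.0 in replicate 6.

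The pkl effect differed between uniconazole and solvent by an interaction of 0.86 for OLEO3, 0.87 for LEA, -0.99 for XTH19 and -0.91 for scpl44. Among gene groups the mean difference was 0.32 ± 0.11 (SE) for seed maturation genes and 0.18 ± 0.20 for chloroplast-encoded genes, of which 0 of 69 passed singly. Neither call held with an estimated correlation (camera adjusted p = 0.305 and adjusted p = 0.834). The chloroplast-encoded difference was smaller than its standard error. With the share of probe sets under a signal of 16 as a covariate, the pkl effect on the chloroplast-encoded score was 0.37 ± 0.11 in solvent. In uniconazole it was then 0.39 ± 0.12, which leaves little difference between the conditions. The covariate was chosen after seeing the data.

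Chance was argued against for the counts of changed probe sets in the 4 contrasts between 2 groups by 100 splits of the arrays in each. The smallest share these splits could reach was 1 in 100, and they do not test a processing difference that followed the groups. The pkl comparison in solvent called 2672 and the highest other split 1172, the pkl comparison in uniconazole 4222 and 1027, uniconazole in wild type 3755 and 1463, and uniconazole in pkl 4999 and 1937, so in each case 1 split, the real one, gave as many. For the interaction, 2 of 100 splits gave at least the 32 of the real one, and the other of them called 135. A count several times the real one points to a structure of the samples, and in that split 2 of the 6 solvent arrays of the wild type and 5 of the 6 of pkl kept their treatment, so the treatment effects entered the interaction and these splits do not settle chance. After the genotype and treatment effects were removed from each probe set, 1 of 100 arrangements of the arrays, the real one, gave 32, and the highest other gave 6.

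The first pattern weighed was the higher level of chloroplast-encoded transcripts in pkl under uniconazole, 0.51 ± 0.14 (SE) in the score. A greater carry-over of RNA without poly(A) tails from both organelles alike is argued against by the 16 mitochondrion-encoded genes. Their difference was -0.03, below the chloroplast-encoded one by 0.54 ± 0.16. They were dimmer, with scores under uniconazole of 8.33 in wild type and 8.30 in pkl, against 11.50 and 12.01. A carry-over limited to plastid RNA was not tested. Leaving out any 1 of the 12 arrays kept the chloroplast-encoded difference between 0.41 and 0.60, against a single array as the source. With the share of probe sets under a signal of 16 as a covariate, which 566 probe sets followed within groups, it was 0.39 ± 0.12, which argues against array quality, as far as that share follows it, as the whole cause. RNA integrity stays open, since with the GAPDH and actin 3′/5′ ratios as covariates it was 0.51 ± 0.16, the same with ubiquitin added, but in limma 0 probe sets followed the first 2 (1813 at an unadjusted p under 0.05), as do a part played by array quality and an effect of pkl on plastid transcripts.

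The second pattern was the larger response of seed maturation genes to uniconazole in pkl. The 13 members above the bacterial control level in all groups had a mean interaction of 0.25 ± 0.09 (SE) and the 2 others 0.75 ± 0.34. This met the outcome written down beforehand for compression of low signals. With only 2 dimmer members and a standard error of 0.34, it does not decide whether compression accounts for part of the pattern. The 13 brighter members lay above 0 by more than 2 standard errors, but that comparison was not written down beforehand. A single array is argued against by a lowest interaction of 0.26 with 1 of 24 arrays left out. A dependence of the response on PICKLE stays open as a hypothesis.

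The third pattern was the rise of seed maturation genes with uniconazole in wild type. If treated seeds were only at an earlier stage of germination, nuclear photosynthesis genes, which rise as seedlings green, would be lower. Their score was higher by 0.40 ± 0.08 (SE), which argues against a uniform delay as the only effect of treatment. It does not decide the cause of the seed maturation rise, since uniconazole may raise photosynthesis genes apart from any delay. The call of the nuclear photosynthesis list was also lost with an estimated correlation (camera adjusted p = 0.171). A delay limited to some tissues, and a direct response to lower gibberellin, were not tested. Nor was a part played by abscisic acid or brassinosteroid, whose gene lists had 0 named members. A difference in stage between pkl and wild type was not tested either. The nuclear photosynthesis score differed in pkl by -0.26 ± 0.08 (SE) in solvent and -0.19 ± 0.08 in uniconazole. The seed maturation score differed by 0.38 ± 0.08 and 0.70 ± 0.08. An earlier stage of pkl would give these directions, so it stays open.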

How the results depend on the processing

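Single-array fits and those with covariates were chosen after seeing the data. The 265 named gene results gave 3893 values under alternatives, of which 3821 kept direction and side of the threshold, 67 no longer passed, 5 newly passed and 0 changed direction. The 32 list calls gave 348 values, of which 313 kept the call, 35 lost it and 0 changed direction. With an estimated correlation 8 list calls were left in place of 32. At a threshold of 0.01 the counts were 1505 for pkl in solvent, 2484 for pkl in uniconazole, 2155 for uniconazole in wild type and 10 for the interaction, by construction. With the GAPDH and actin ratios as covariates uniconazole in wild type gave 2422, with 359 log2 changes of at least 1 in place of 358. The interaction count of 32 became 20 with no variance trend, 20 without wt replicate 5, 39 without wt replicate 2, 22 without wt replicate 1, 21 without Uwt replicate 2 and 19 with the low-signal share as covariate; the cause was not tested. The correlation of the pkl effects was 0.46 with an offset of 1, 0.70 with an offset of 64 and 0.81 with the filter on low signal, and that of the uniconazole effects 0.49, 0.75 and 0.86; the cause was not tested. The replicate numbers were not taken to pair the samples. Over 36 pairs the correlation of same-numbered arrays ran from -0.087 to 0.18, and 7 were over 0.1. In 10 of the 36 an array correlated best with its own number, where unrelated numbers would give about 1 in 6. Most of these matches lay among wild type and pkl with solvent and wild type with uniconazole. For wt with pkl in solvent all 6 were positive (0.038 to 0.131) and 4 were best. A batch shared by same-numbered arrays of these groups is not excluded, and the main fit does not model one. With the number as a block the counts were 3037, 4666, 4128, 5342 and 33 in the order of the report, in place of 2672, 4222, 3755, 4999 and 32. Signals near the bacterial control level limit the rest: 3950 of 22746 probe sets had every group mean at or under it.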

Other observations

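Some of the largest changes belonged to genes with a locus code only, chosen here after their values were seen. AT4G14090 had a mean signal of 34.3 in wild type with solvent, under the bacterial control level, 121 ± 36.1 in pkl with solvent, and 658 ± 114 and 1610 ± 154 in wild type and pkl with uniconazole (SD, n = 6). It was at least 11.99-fold higher with uniconazole in wild type, and in pkl its log2 change was 3.61. AT4G36700 rose with uniconazole from 522 ± 112 to 2526 ± 550 in wild type and from 772 ± 177 to 5392 ± 548 in pkl. AT2G43860 had 699 ± 179 in wild type with solvent, 121 ± 40.9 in pkl with solvent, 529 ± 258 in wild type with uniconazole and 10.0 ± 4.4 in pkl with uniconazole. The last mean was under the bacterial control level, so the gene was at least 9.64-fold lower in pkl than in wild type with uniconazole, and the size of its interaction, past the threshold in limma (adjusted p = 0.0256), is not given. AT1G21520 had 291 ± 67.3 in pkl with uniconazole and means of 25.3 to 49.5 in the other groups, all under the bacterial control level, so it was at least 5.31-fold higher in pkl than in wild type with uniconazole (limma interaction, adjusted p = 1.24e-05).

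Further gene groups were examined. Of 16 mitochondrion-encoded genes, 1 rose and 1 fell in each pkl contrast, 0 changed with uniconazole in wild type and 2 rose with it in pkl (camera adjusted p from 0.589 to 0.877 over the 4 contrasts between groups). Of 989 annotated pseudogenes, 5 rose and 2 fell in the pkl contrast in solvent, 23 and 4 in uniconazole, 2 and 6 with uniconazole in wild type, and 8 and 7 with it in pkl (camera adjusted p from 0.374 to 0.978). The cell division gene AUR1 (log2 change -0.33, adjusted p = 0.0774) and PDF1.2, of pathogen response (-0.40, adjusted p = 0.206), did not pass in pkl with solvent. PDF1.2 did not pass in pkl with uniconazole either (-0.42, adjusted p = 0.141). In each of these results the unadjusted p was under 0.05, and adjustment over a list with 1 named gene leaves it as it is. BAN, of the testa, had means of 8.1 to 14.5 in the 4 groups, under the bacterial control level.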
